A study of Homo sapiens with 12 samples.

How the data were processed

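Gene expression was measured on 12 arrays: 3 human cancer cell lines (PC-3, HBC4, MKN74), each with 4 treatments (reagent alone, (uuaccc)4, (uuaggg)4, AS1411), with 1 Affymetrix human genome array per line and treatment. Per the labels' protocols, total RNA was extracted on RNeasy columns and biotin-labelled cRNA was made from 100 ng. The deposited values are log2 expression values; RMA is named in the submitters' processing notes, with no version given in the sources used here. In the deposited table each of the 54675 probe sets has a median of 0 over the 12 arrays, to within 5e-07, so the values were centred per probe set after RMA, by a step not given in the sources used here. The base of the logarithm was taken as 2 because the highest value lies 11.2 above its probe set's median. Centring leaves differences between arrays intact but removes each probe set's level, so no level, no detection call and no depth can be given, and a value near a probe set's background cannot be recognised.

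The design fixed before the data were examined assumed uncentred values, and 3 of its settings were changed for this reason. No intensity filter was applied. The variance prior of limma was fitted without an intensity trend, and the planned trend is an alternative. A gene with several probe sets was represented by the probe set with the largest SD of the 3 line means, in place of the brightest. A line mean holds all arrays of the line, G4 arrays included. The choice can therefore favour probe sets whose response differs between lines, which bears on the interaction and on the results within lines. Averaged probe sets and all probe sets are alternatives. Of the probe sets, 62 were array controls and stayed out of the tests, 41091 named 1 gene, 1801 named several and were left out, and 11721 are unnamed here. Gene names come from the platform annotation of 2016, checked through gene identifiers against RefSeq genes of GRCh38.p14 (41037 probe sets matched and 0 symbols changed); no coordinates were used. This gave 19775 genes, of which 10523 had several probe sets. Where probe sets of a named gene past the threshold, or named by size, disagreed in sign, the text says so. Probe sets that agreed in sign can still differ in size, which the text gives for some genes only. Members of the gene lists without a probe set named here count as unmeasured.

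Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), on all 12 arrays. The treatment model held treatment and cell line, with 6 residual degrees of freedom; G4 oligonucleotides against controls was the mean of (uuaggg)4 and AS1411 minus the mean of the reagent alone and (uuaccc)4. The cell line is a block, since the replicate number in each treatment stands for the same line. Arrays of a line correlated at 0.892 or more, and arrays of different lines at -0.174 or less, the latter lowered by the centring. The labels name no further cultures, so within a line the spread is that between arrays of different treatments. The line model held cell line and an oligonucleotide class effect per line, also with 6 residual degrees of freedom, in which the 2 arrays of a class count as replicates, and the interaction is its F test. Adjusted p-values are Benjamini-Hochberg over all genes, with a threshold of 0.05. SD is that of the 3 line differences; SE and intervals (95%) are those of the fit.

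Gene lists (20) were fixed before the data were examined: interferon-stimulated genes, MHC class I, NF-kB and cytokines, nucleic acid sensors, telomere maintenance, G4-binding proteins, ribosome biogenesis, MYC targets, p53 targets, cell division, DNA replication, ATF4 and unfolded protein response, heat shock, hypoxia, cholesterol synthesis, epithelial and mesenchymal genes, immediate early genes, metallothioneins and stemness markers. Markers of 7 cell types were fixed likewise. Lists were tested with camera (preset correlation 0.01), with camera at an estimated correlation, with fry, which tests whether the members move on balance in a single direction, and for the G4 comparison by exact permutation of the list mean within lines, all adjusted over the 20 lists. Named genes follow a rule fixed in advance: for the G4 comparison the 12 largest log2 fold changes in each direction past the threshold with the same sign in 3 lines; for the others up to 6 in each direction, within a line with both G4 arrays beyond both control arrays; the 8 smallest interaction p-values; up to 4 genes of a direction by size (0.58 or more in each line) where fewer than 4 passed; the 4 members of each list with the smallest p, of which the text prints those past the threshold, the leading ones of a large list and some of the largest values that did not pass; and NCL, ISG15, OAS3, TERF1, TERF2 and DHX36. List members beyond these 4, where named, were chosen after their values were seen.

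The scripts were tested on simulated data: 12 arrays with the real line means and residual spreads, and 200 of 19775 genes shifted. For G4 oligonucleotides against controls 61.2% of shifts of 0.5, 97.0% of shifts of 1 and 100.0% of shifts of 2 were recovered, with 8 unshifted genes among 180 calls. For (uuaggg)4 against (uuaccc)4 the shares were 35.8%, 86.6% and 98.5%. Comparisons simulated without a difference called 0 genes. The interaction was among them, so the simulated shifts did not differ between lines. Real responses did: TRIM22 (-1.85, SD 1.85) and RTP4 (-1.31, SD 1.80) did not pass for G4 oligonucleotides against controls. Regrouping the real arrays within lines, other than by exchanging the classes of whole lines, gave up to 272 interaction genes. The simulated shares and the 0 may therefore not carry over to the real data. Alternatives tried were array median centring, quantile normalization of the centred values, probe set choices, the intensity trend, array weights, no line block, fits on 6 arrays, a 2-class model, exchanged controls, and leaving out each line and each array; a filter on the spread between line means (the top 60% kept) was added after the values were seen. Intensity filters could not be set on centred values.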

Results

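The series profiled gene expression in 3 human cancer cell lines that had taken up short nucleic acids able to fold into G-quadruplexes (G4), 4-stranded structures built on stacked guanines. Per the labels PC-3 is a prostate, HBC4 as a breast and MKN74 as a gastric cancer line. Each line received 4 treatments by reverse transfection with Lipofectamine RNAiMAX: the reagent alone, the RNA oligonucleotide (uuaccc)4, the RNA oligonucleotide (uuaggg)4, or the DNA oligonucleotide AS1411. (uuaggg)4 carries the repeat of telomeric RNA and folds into a G4, (uuaccc)4 is the repeat with its guanines replaced by cytosines, and AS1411 is a guanine-rich G4 aptamer that binds nucleolin. About 100 pmol per well was given to 300000 cells, which were kept in 3D culture on a low-adhesion surface and harvested after 72 h. Total RNA was measured on 12 Affymetrix arrays, 1 per line and treatment, so each treatment had 3 arrays from 3 different lines. The number of arrays limits the precision. Behind each p-value of a treatment comparison stands a single spread per gene, what cell line and treatment leave unexplained, pooled over the 4 treatments. It is not the SD of that comparison's own 3 line differences. Within a line, and for differences between lines, the spread is that between arrays of different treatments in the same class. Arrays separated first by line: over the 19775 genes tested the lowest correlation within a line was 0.892 and the highest between lines was -0.174. Centring each probe set lowers correlations between lines, and probe sets were chosen for their spread between lines, so part of this contrast is built in.

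The main question was what the G4-forming oligonucleotides changed against the 2 controls. Genes that cells switch on in response to interferon fell in all 3 lines with both G4 oligonucleotides. The largest declines among genes past the threshold were those of IFI27 (log2 fold change -3.82 ± 2.25, SD over n = 3 lines, 14.1-fold lower, adjusted p = 0.00691), the antiviral enzyme RSAD2 (-3.22 ± 1.39, 9.31-fold lower, adjusted p = 0.00134) and IFI44 (-3.16 ± 0.27, 8.94-fold lower, adjusted p = 2.07e-07). Genes that rose changed by less, among them CDC20, the activator of the anaphase-promoting complex (0.55 ± 0.25, adjusted p = 0.00806), the mitotic kinase NEK2 (0.57 ± 0.16, adjusted p = 0.00541) and the chromatin remodeller HELLS (0.62 ± 0.17, adjusted p = 0.00488). The lowest of the 5 probe sets of HELLS gave 0.09. In all, limma placed 515 genes past an adjusted p of 0.05, 351 lower and 164 higher, and each had the same direction in the 3 lines. Of the genes past the threshold, 72 fell and 1 rose by at least 2-fold.

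**Figure D1:**
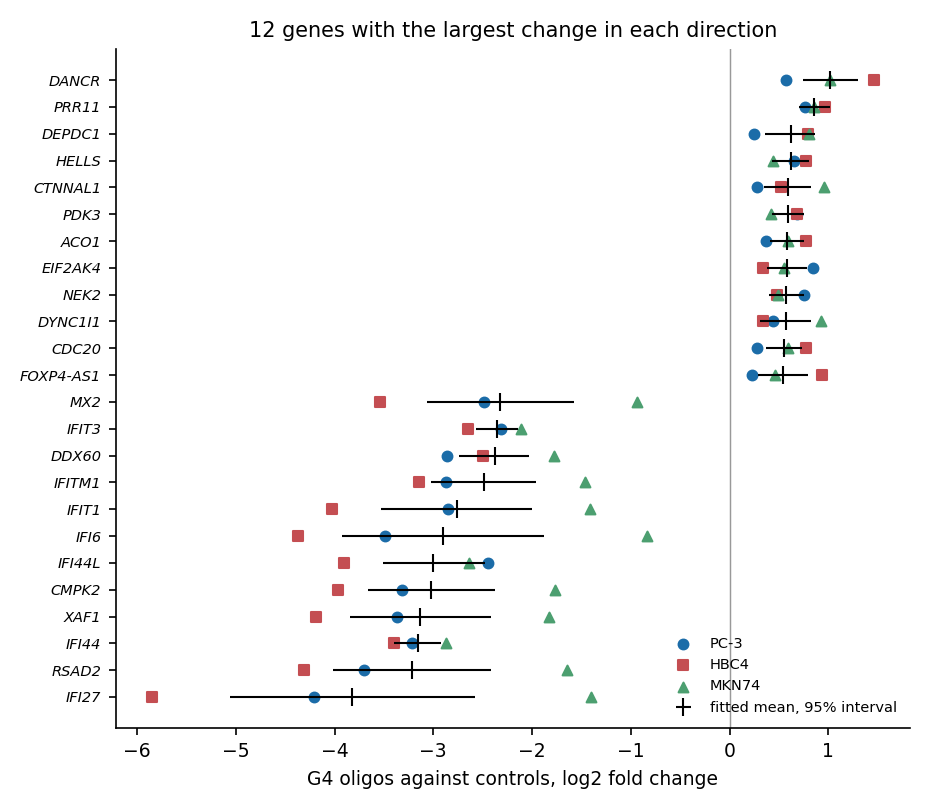
Log2 fold change of G4 oligonucleotides against controls (x axis) for the 12 genes past the threshold with the largest change in each direction. Symbols give the value in each cell line, and black bars the fitted mean with its 95% interval. IFI44 and IFIT3 lie close together in the 3 lines, while IFI27 runs from -5.85 in HBC4 to -1.40 in MKN74.

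Of the 60 measured interferon-stimulated genes, 56 fell over all genes tested and 60 fell when adjusted over the list alone. The list's median log2 fold change was -1.77, with quartiles of -2.29 and -1.15 (camera adjusted p = 3.15e-78, and adjusted p = 0.0322 with an estimated correlation). In an exact two-sided permutation of the array means within lines the list differed at p = 0.00926, the smallest value the design can give (adjusted p = 0.0265 over the 20 lists). Fry gave an adjusted p of 6.05e-04. The fall covered effectors that restrict viruses, such as IFIT1 (-2.76 ± 1.31, adjusted p = 0.00251), IFITM1 (-2.49 ± 0.90, adjusted p = 4.19e-04) and MX2 (-2.32 ± 1.31, adjusted p = 0.00629), the ubiquitin-like modifier ISG15 (-2.15 ± 1.07, adjusted p = 0.00287) and its conjugating enzyme UBE2L6 (-1.58 ± 0.20, adjusted p = 4.55e-06). It also covered XAF1 (-3.13 ± 1.20), CMPK2 (-3.02 ± 1.13), IFI6 (-2.90 ± 1.84), DDX60 (-2.38 ± 0.55) and IFIT3 (-2.36 ± 0.27), and IFI44L, which was 7.99-fold lower (adjusted p = 1.29e-04). The 4 members that did not pass over all genes were TRIM22 (-1.85, adjusted p = 0.0654), DHX58 (-0.35, adjusted p = 0.0664), RTP4 (-1.31, adjusted p = 0.153) and GBP2 (-0.62, adjusted p = 0.2).

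Nucleic acid sensors and adaptors fell as a list (24 measured, median -0.39, camera adjusted p = 7.07e-15, and adjusted p = 0.0322 with an estimated correlation). Over all genes 10 of them fell and 15 fell when adjusted over the list alone. Of those 10, 6 are also members of the interferon-stimulated list. The RNA-binding synthetases OAS1 (-2.31 ± 0.57, adjusted p = 5.88e-05), OAS2 (-2.29 ± 0.87, adjusted p = 6.59e-04) and OAS3 (-1.88 ± 0.74, adjusted p = 7.37e-04) and the DNA sensor IFI16 (-2.08 ± 0.53, adjusted p = 4.46e-04) had the smallest p. The adaptors MAVS (0.07, adjusted p = 0.74) and STING1 (-0.09, adjusted p = 0.679) and the transcription factor IRF3 (-0.01, adjusted p = 0.962) did not pass. Genes of MHC class I antigen presentation fell too (18 measured, median -0.55, camera adjusted p = 3.14e-15, and adjusted p = 0.00241 with an estimated correlation), 11 of them over all genes and 14 adjusted over the list alone. Among them were the peptide transporter subunit TAP1 (-1.35 ± 0.47, adjusted p = 4.19e-04) and the class I heavy chains HLA-C (-0.95 ± 0.35, adjusted p = 0.00134), HLA-E (-0.87 ± 0.31, adjusted p = 0.00333) and HLA-F (-1.04 ± 0.52, adjusted p = 0.0059). In the list of NF-kB and inflammatory cytokine genes (26 measured, median -0.23), 3 fell over all genes. These were LCN2 (-0.65 ± 0.34, adjusted p = 0.0173), TNFAIP2 (-0.37 ± 0.17, adjusted p = 0.0425, with another probe set at 0.06) and ICAM1 (-0.55 ± 0.45, adjusted p = 0.0491, with another probe set at -0.03). Complement factor CFB had -1.09 ± 0.92 without passing (adjusted p = 0.0526, with another probe set at 0.17). Adjusted over the list alone 10 fell and 1 rose. The list's camera call (adjusted p = 9.40e-06) was lost with an estimated correlation (adjusted p = 0.0899). The exact permutation within lines gave an adjusted p of 0.0265, and fry 0.0135.

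**Figure D2:**
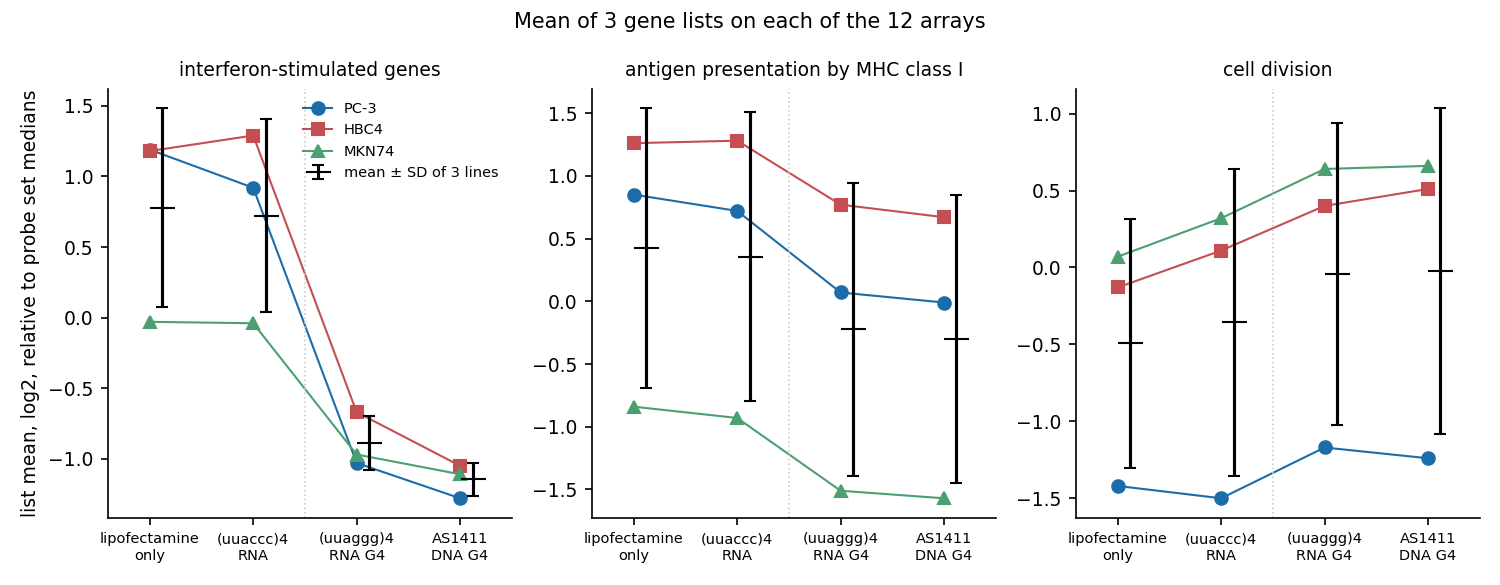
Mean log2 value of 3 gene lists, relative to each probe set's median over the arrays (y axis), on each of the 12 arrays by treatment (x axis); coloured symbols are the 3 cell lines, black bars the mean ± SD of the 3 lines, and the dotted line parts controls from G4 oligonucleotides. The interferon-stimulated genes of PC-3 stand at 1.19 with the reagent alone and at -1.28 with AS1411.

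The list of cell division genes rose (26 measured, median 0.39, camera adjusted p = 3.53e-24), with 18 members higher over all genes and 25 adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.0899), while the exact permutation within lines gave an adjusted p of 0.0265, and fry 0.00264. Its leading members were the mitotic kinase AURKB (0.48 ± 0.08, adjusted p = 0.0035), the ubiquitin-conjugating enzyme UBE2C (0.44 ± 0.13, adjusted p = 0.00737) and the cyclin CCNB2 (0.51 ± 0.18, adjusted p = 0.00861). Another probe set of AURKB gave 0.04, as did another of CCNB2. DNA replication genes had a median of 0.28 (27 measured), and 4 rose over all genes and 21 adjusted over the list alone. The 4 were RRM2 (0.47 ± 0.16, adjusted p = 0.0157) and TYMS (0.36 ± 0.08, adjusted p = 0.0174), which supply deoxynucleotides, the primase subunit PRIM1 (0.39 ± 0.11, adjusted p = 0.0174) and GINS2 (0.45 ± 0.20, adjusted p = 0.0374). The lowest probe set values were 0.28 for RRM2, 0.12 for TYMS and 0.02 for GINS2. That list's camera adjusted p of 2.15e-14 became an adjusted p of 0.233 with an estimated correlation. The exact permutation within lines gave an adjusted p of 0.0265, and fry 0.0324. Among single genes past the threshold, the non-coding RNA DANCR had the largest rise (1.02 ± 0.44, 2.02-fold, adjusted p = 0.00248), followed by PRR11 (0.86 ± 0.11, adjusted p = 1.84e-04). Another of the 3 probe sets of PRR11 gave -0.00. DEPDC1 (0.62 ± 0.32), the pyruvate dehydrogenase kinase PDK3 (0.59 ± 0.15), CTNNAL1 (0.59 ± 0.35), the iron-responsive aconitase ACO1 (0.58 ± 0.20), the dynein chain DYNC1I1 (0.57 ± 0.32) and FOXP4-AS1 (0.54 ± 0.36) also rose, as did EIF2AK4 (0.58 ± 0.26), whose other probe set gave -0.12. Lowest probe set values were 0.02 for DYNC1I1, 0.12 for ACO1, 0.20 for PDK3 and 0.26 for DEPDC1.

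Of the genes closest to the oligonucleotides' known targets, few passed. Nucleolin, NCL, the protein that AS1411 binds, had a log2 fold change of 0.07 ± 0.07 (adjusted p = 0.574). The telomere-binding proteins TERF1 (-0.11 ± 0.12, adjusted p = 0.414) and TERF2 (0.13 ± 0.20, adjusted p = 0.444) and the G4 helicase DHX36 (-0.19 ± 0.12, adjusted p = 0.232) did not pass. None of 21 shelterin, telomerase and telomere maintenance genes passed over all genes (median -0.02, camera adjusted p = 0.879); adjusted over the list alone 1 rose and 1 fell. The chromatin remodeller ATRX had the smallest p of that list and a log2 fold change of -0.72 ± 0.34 (adjusted p = 0.0537). It was negative in all 3 lines (-1.06 in PC-3, -0.72 in HBC4 and -0.39 in MKN74) and on its 4 probe sets, which ranged from -0.72 to -0.02. Of 23 G4-binding proteins and helicases 1 fell, FMR1 (-0.28 ± 0.06, adjusted p = 0.0305; list median -0.02, camera adjusted p = 0.876), and 1 fell adjusted over the list alone. Nucleolus and ribosome biogenesis genes (24 measured, median 0.08) had 1 riser, the methyltransferase FBL (0.40 ± 0.12, adjusted p = 0.0143), also the only riser adjusted over the list alone, and a camera adjusted p of 5.39e-04 that was lost with an estimated correlation (adjusted p = 0.527). MYC and its targets (18 measured, median 0.11, 0 past the threshold on either count) had a camera adjusted p of 0.00387 and an adjusted p of 0.421 with an estimated correlation. By exact permutation within lines the adjusted p was 0.0265 for MYC targets and 0.0741 for ribosome biogenesis. With fry it was 0.079 for MYC targets and 0.108 for ribosome biogenesis.

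Of 23 p53 target genes 2 fell, TP53INP1 (-0.54 ± 0.30, adjusted p = 0.0194), for which 1 of 3 probe sets had this sign, and PHLDA3 (-0.30 ± 0.12, adjusted p = 0.0436), and 4 fell adjusted over the list alone. The list median was -0.16, with a camera adjusted p of 1.35e-04 and an adjusted p of 0.233 with an estimated correlation. By exact permutation within lines the adjusted p was 0.0463, and with fry it was 0.0628. Single members fell in 3 further lists that camera did not call: INSIG2 among 26 hypoxia and glycolysis genes (-0.33 ± 0.09, adjusted p = 0.0423; list median 0.03), the mucin MUC1 among 21 epithelial adhesion genes (-0.48 ± 0.25, adjusted p = 0.0307; list median -0.06) and the receptor kinase AXL among 23 mesenchymal genes (-0.36 ± 0.22, adjusted p = 0.046, with another probe set at 0.04; list median -0.06). Adjusted over the list alone the counts of falling members in these 3 lists were 1, 4 and 2. Large values without a pass were those of the adhesion molecule CEACAM6 (-0.90 ± 0.80, adjusted p = 0.0623) and fibronectin, FN1 (-0.70 ± 0.67, adjusted p = 0.0631, 6 of 7 probe sets with this sign). The remaining lists had no member past the threshold over all genes and no camera call: ATF4 and unfolded protein response (median -0.02), heat shock and proteotoxic stress (0.06), cholesterol synthesis (0.00, with 1 lower adjusted over the list alone), immediate early genes (0.00), metallothioneins and oxidative stress (0.05) and stemness and tumour-initiating cell markers (0.03).

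Without HBC4, PC-3 or MKN74 the count of 515 became 48, 131 or 173, and after quantile normalization 314. Without 1 array it lay between 211 ((uuaggg)4 in HBC4) and 420 (AS1411 in PC-3), and without the cell line as a block it was 1.

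The comparison of (uuaggg)4 with (uuaccc)4 sets 2 RNA oligonucleotides of the same length side by side, of which only the former can form a G4. Interferon-stimulated genes again led: IFI44 fell 7.86-fold (log2 fold change -2.97 ± 0.22, adjusted p = 1.60e-05), XAF1 7.9-fold (-2.98 ± 0.92, adjusted p = 0.0301), CMPK2 7.02-fold (-2.81 ± 1.15, adjusted p = 0.0261) and IFI44L 6.62-fold (-2.73 ± 0.63, adjusted p = 0.00855). DDX60 (-2.27 ± 0.52, adjusted p = 0.00317) and IFITM1 (-2.25 ± 0.90, adjusted p = 0.0295) followed. In total 46 genes fell and 2 rose, PRR11 (0.76 ± 0.11, adjusted p = 0.0158, with another probe set at -0.16) and CMTM4 (0.54 ± 0.04, adjusted p = 0.034). FLT1, a receptor for vascular endothelial growth factor, had a log2 fold change of 0.82 ± 0.21 without passing (adjusted p = 0.0986, 5 of 6 probe sets with this sign).

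Of the 60 interferon-stimulated genes 24 fell over all genes and 57 adjusted over the list alone (median -1.62, camera adjusted p = 1.52e-74, and adjusted p = 0.0461 with an estimated correlation). MHC class I genes (median -0.52, 1 lower and 11 adjusted over the list alone) and nucleic acid sensors (median -0.38, 4 lower and 11 adjusted over the list alone) also fell as lists, with adjusted p = 0.00478 and 0.0461 under an estimated correlation. Cell division genes had a median of 0.33, with 0 past the threshold over all genes and 17 higher adjusted over the list alone (camera adjusted p = 5.32e-16, adjusted p = 0.0459 with fry, and adjusted p = 0.179 with an estimated correlation). The camera calls of DNA replication (median 0.24), NF-kB genes (-0.22), p53 targets (-0.12) and ribosome biogenesis (0.05) were lost in the same way, at adjusted p = 0.528, 0.121, 0.548 and 0.732 with an estimated correlation. Without PC-3 or HBC4 the count of 48 became 2 or 9, and without the array of (uuaggg)4 or (uuaccc)4 it became 8 or 13 for PC-3, 7 or 12 for HBC4 and 26 or 28 for MKN74. Without the reagent array of HBC4 it was 25, with only the 6 arrays of these 2 treatments 10, after quantile normalization 12, and without the cell line as a block 0.

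AS1411 was set against the reagent alone, since it is a DNA oligonucleotide without a matched control here. RSAD2 fell 11.3-fold (-3.50 ± 1.61, adjusted p = 0.014), IFI44 10.2-fold (-3.35 ± 0.35, adjusted p = 4.60e-06), XAF1 9.68-fold (-3.27 ± 1.49, adjusted p = 0.0103) and IFI44L 9.65-fold (-3.27 ± 0.95, adjusted p = 0.00196). CMPK2 fell 9.4-fold (-3.23 ± 1.16, adjusted p = 0.00581) and IFIT1 8.91-fold (-3.16 ± 1.48, adjusted p = 0.0195). DANCR rose 2.07-fold (1.05 ± 0.47, adjusted p = 0.0319), PRR11 1.95-fold (0.96 ± 0.22, adjusted p = 0.00262), the kinetochore protein SPC25 1.72-fold (0.78 ± 0.34, adjusted p = 0.0353) and HELLS 1.69-fold (0.76 ± 0.29, adjusted p = 0.0242). The ribosomal protein gene RPL35A (0.65 ± 0.08, adjusted p = 0.0373) and NEK2 (0.64 ± 0.02, adjusted p = 0.0402) rose as well. The lowest probe set values were 0.06 for RPL35A, 0.38 for NEK2 and 0.13 for HELLS. Altogether 98 genes fell and 17 rose; without the reagent array of PC-3 these counts were 52 and 34.

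Of the interferon-stimulated genes 38 fell over all genes and 59 adjusted over the list alone (median -1.88, camera adjusted p = 1.36e-76, and adjusted p = 0.0339 with an estimated correlation). MHC class I genes (median -0.70, 4 lower and 13 adjusted over the list alone) and nucleic acid sensors (median -0.50, 8 lower and 12 adjusted over the list alone) fell with adjusted p = 0.00252 and 0.0339 under an estimated correlation. Cell division genes had 5 members higher over all genes and 24 adjusted over the list alone (median 0.46, camera adjusted p = 9.42e-26, adjusted p = 0.00603 with fry, and adjusted p = 0.0894 with an estimated correlation). Camera also called DNA replication (median 0.35), NF-kB genes (-0.23), p53 targets (-0.20), MYC targets (0.13), ribosome biogenesis (0.10), epithelial genes (-0.10) and mesenchymal genes (-0.09), none of which held with an estimated correlation (adjusted p = 0.231, 0.205, 0.225, 0.324, 0.41, 0.361 and 0.361). Without HBC4 or PC-3 the count of 115 became 8 or 28, and without the AS1411 array it became 38 for PC-3, 39 for HBC4 and 71 for MKN74. Without the reagent array of HBC4 or MKN74 it was 36 or 62, with only the 6 arrays of these 2 treatments 23, after quantile normalization 61, and without the cell line as a block 0.

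The lists of the 2 oligonucleotides overlapped although they share no control array. Of the 46 genes lower with (uuaggg)4 and the 98 lower with AS1411, 41 were shared, where independent lists would share 0.228. Of the 2 and 17 higher genes 1 was shared, where independent lists would share 0.00172. Both lists rest on the same estimate of each gene's spread, so they are not independent and these expectations can be too low. Across all genes the 2 sets of log2 fold changes correlated at a Pearson r of 0.64 and a Spearman rho of 0.43, with a covariance of 0.0297; genes are not independent replicates. Within lines, 100 random reassignments of the treatments gave r from -0.63 to 0.68, and 3 of them were as high as the real one. A reassignment that keeps or exchanges the 2 classes of whole lines leaves the shared response in both comparisons. A high r can then be built in, and whether the 3 were of this kind was not examined. With the controls exchanged r was 0.64.

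**Figure D3:**
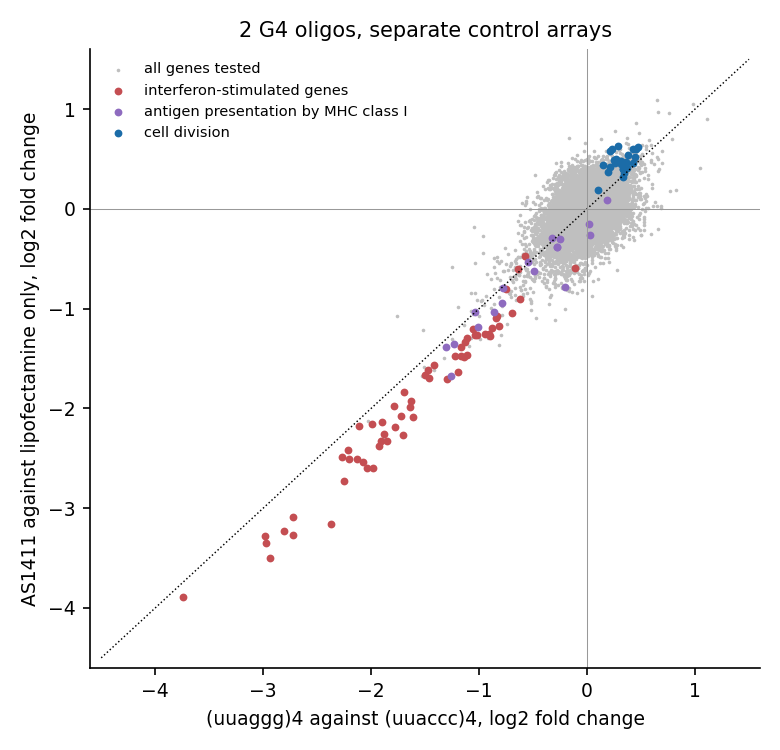
Log2 fold change of each gene for (uuaggg)4 against (uuaccc)4 (x axis) and AS1411 against the reagent alone (y axis); grey points are all 19775 genes, coloured points 3 gene lists, and the dotted diagonal marks equal change. Interferon-stimulated genes extend along the diagonal to the lower left, with medians of -1.62 and -1.88.

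The controls were compared with each other to see what an RNA oligonucleotide without a G4 does. No gene passed between (uuaccc)4 and the reagent alone (0 of 19775 by limma, with 567 genes at an unadjusted p under 0.05, where chance gives 989). The spread used was pooled over all treatments. Responses to G4 oligonucleotides that differ between lines can widen it, so small differences between the controls could be missed. Interferon-stimulated genes had a median of -0.06 (camera adjusted p = 0.4), MHC class I genes -0.09 and nucleic acid sensors -0.05. Cell division genes had a median of 0.12 (camera adjusted p = 2.33e-08), DNA replication genes 0.05 (adjusted p = 0.0462) and mesenchymal genes -0.10 (adjusted p = 0.0462). No member passed, also when adjusted over the list alone, and all 3 calls were lost with an estimated correlation (adjusted p = 0.844 for each). Still, all 26 cell division genes were positive. With the reagent alone, (uuaccc)4 and (uuaggg)4 the mean of that list was -0.13, 0.11 and 0.40 in HBC4. It was 0.07, 0.32 and 0.64 in MKN74, and -1.42, -1.50 and -1.17 in PC-3. The rise of cell division genes against the reagent alone is therefore not shown to be particular to G4 oligonucleotides. Against (uuaccc)4, all 26 were positive with (uuaggg)4, with a median of 0.33. There fry gave an adjusted p of 0.0459, and camera with an estimated correlation 0.179.

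The RNA and the DNA G4 oligonucleotide differ in their sugar, their sequence and their length. No gene passed between (uuaggg)4 and AS1411 (0 by limma; 893 genes with an unadjusted p under 0.05, where chance gives 989). Of the 60 interferon-stimulated genes 58 had the higher value with (uuaggg)4, with a median of 0.24; the camera call (adjusted p = 1.09e-06) was lost with an estimated correlation (adjusted p = 0.696). The list mean was higher with (uuaggg)4 by 0.25 in PC-3, 0.38 in HBC4 and 0.15 in MKN74 (0.26 ± 0.12, SD, n = 3), and the exact two-sided sign-flip test gave p = 0.25, the smallest 3 lines allow. Metallothionein and oxidative stress genes had a median of -0.12 (camera adjusted p = 0.00954, and adjusted p = 0.239 with an estimated correlation), ATF4 genes 0.08 and ribosome biogenesis genes -0.06 (adjusted p = 0.0394 for both, and adjusted p = 0.696 with an estimated correlation). By size alone, the cohesin loader NIPBL (0.81 ± 0.25) and the kinase CDC42BPA (0.81 ± 0.37) stood highest in all 3 lines, neither past the threshold (adjusted p = 0.76 and 1), and 2 of the 5 probe sets of each had the opposite sign.

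Within single lines, the 2 G4 arrays were set against the 2 control arrays. In PC-3, 256 genes fell and 126 rose. IFI27 fell 18.5-fold (log2 fold change -4.21, SE 0.15, adjusted p = 6.57e-07), the tethering factor BST2 15.4-fold (-3.95, adjusted p = 2.89e-06) and TRIM22 15.4-fold (-3.94, adjusted p = 2.28e-05), followed by RSAD2 (-3.70), IFI6 (-3.49) and HERC6 (-3.37, with another probe set at -0.01). The heat shock genes HSPA6 (2.26, 4.8-fold, adjusted p = 2.28e-05) and DNAJB1 (1.96, 3.9-fold, adjusted p = 5.19e-05, with another probe set at 0.33) rose in this line, 2 of 12 measured members of the heat shock list, whose median was 0.07 (camera adjusted p = 0.105). Fry gave that list an adjusted p of 7.82e-04, with 7 members positive and 5 negative. The chemokine receptor CXCR4 (1.65, adjusted p = 9.24e-04) rose on all 3 probe sets, whereas the probe sets of the glycolytic enzyme ENO1 (2.09), CDCP1 (1.77) and PHLDB2 (1.70) differed. Their lowest values were 0.01, -0.13 and -0.43. Interferon-stimulated genes had 58 members lower (median -2.23, and adjusted p = 0.0204 with an estimated correlation).

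In HBC4, 397 genes fell and 279 rose, a balance that turned to 783 and 892 after quantile normalization. IFI27 fell 57.7-fold (-5.85, SE 0.15, adjusted p = 2.11e-08), IFI6 20.7-fold (-4.37), RSAD2 19.8-fold (-4.31), XAF1 18.2-fold (-4.19), IFIT1 16.4-fold (-4.03) and CMPK2 15.7-fold (-3.97). TPRG1 (1.68, adjusted p = 0.00109), DANCR (1.46, adjusted p = 5.30e-05), PLCXD3 (1.34), the adenylate kinase AK5 (1.19), CLSTN2 (1.12, with another probe set at 0.31) and the cystine transporter SLC7A11 (1.05, adjusted p = 0.00283) had the largest rises among genes past the threshold with both G4 arrays above both control arrays. Interferon-stimulated genes had 57 members lower (median -1.90, and adjusted p = 0.0379 with an estimated correlation). Of 27 DNA replication genes 12 rose (median 0.48, camera adjusted p = 2.98e-18, adjusted p = 0.0067 with fry, and adjusted p = 0.154 with an estimated correlation).

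In MKN74, 272 genes fell and 90 rose. IFI44 (-2.87, 7.29-fold, adjusted p = 5.94e-04), IFI44L (-2.64) and IFIT3 (-2.11) were again among the largest declines, and 41 interferon-stimulated genes fell (median -1.03). The list's camera call (adjusted p = 5.51e-50) was lost with an estimated correlation (adjusted p = 0.083), while fry gave an adjusted p of 0.00402. Of 26 keratinocyte genes, listed after the values were seen, 4 rose, 3 fell and 19 did not pass. The keratins KRT1 (2.64, 6.21-fold, adjusted p = 1.67e-04) and KRT5 (1.67, adjusted p = 2.41e-04), the gap junction protein GJA1 (1.96, adjusted p = 5.94e-04), the calmodulin-like CALML5 (1.87, adjusted p = 0.0121), the lipid carrier FABP4 (1.93, with another probe set at 0.26) and CLCA2 (1.39) rose. The cornified envelope protein LORICRIN fell 8.41-fold (-3.07, adjusted p = 6.02e-04), the sodium channel subunit SCNN1G 5.13-fold (-2.36, adjusted p = 4.95e-05, with another probe set at 0.11) and HCP5 4.23-fold (-2.08). Measured against the other lines, the arrays labelled MKN74 carried high levels of keratinocyte genes in all treatments, with a median of 4.18 over the 26 genes on the log2 scale and 15 of them over 2 higher, while the median of 9 gastric and intestinal markers was -0.01. After quantile normalization the counts were 229 in PC-3, 1675 in HBC4 and 225 in MKN74. Leaving out 1 array of the line took the counts down to between 153 and 238 in PC-3, 193 and 439 in HBC4, and 123 and 201 in MKN74.

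**Figure D4:**
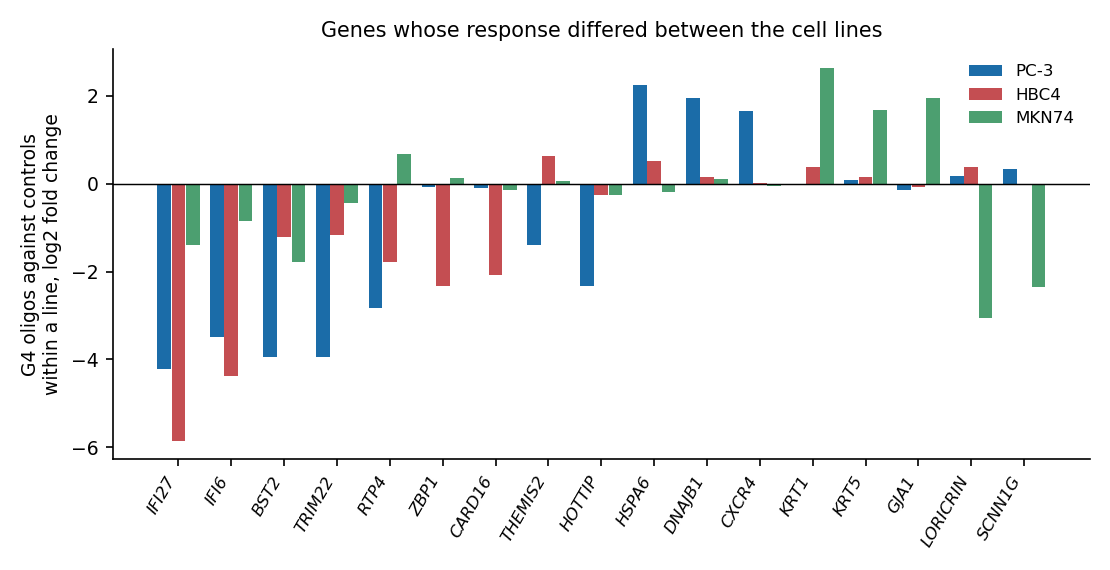
Log2 fold change of G4 oligonucleotides against controls within each line (y axis; bars are the difference of 2 array means per group) for genes named for a line or for the difference between lines (x axis). IFI27 falls in all 3 lines, HSPA6 rises in PC-3 by 2.26, and KRT1 and LORICRIN move apart in MKN74, at 2.64 and -3.07.

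Across lines, 59 genes fell past the threshold in each of the 3 lines and 2 rose, where independent lists would share 0.071 and 0.0081. The 3 lists come from the same line model and share each gene's spread, so these expectations can be too low. The difference between lines was tested as an interaction, which 248 genes passed. IFI27 led (adjusted p = 4.94e-05). It had -4.21 in PC-3, -5.85 in HBC4 and -1.40 in MKN74. IFI6 (-3.49, -4.37 and -0.84, adjusted p = 5.09e-04) and the chaperone RTP4 (-2.83, -1.79 and 0.68, adjusted p = 5.74e-04) likewise had their weakest values in MKN74. The nucleic acid sensor ZBP1 (-0.08, -2.34 and 0.12, adjusted p = 4.24e-04) and CARD16 (-0.09, -2.07 and -0.14, adjusted p = 5.09e-04) had their lowest values in HBC4. Averaged over the lines, the 2 probe sets of ZBP1 gave -0.76 and -0.25, and those of CARD16 -0.76 and -0.06. The non-coding RNA HOTTIP (-2.34, -0.26 and -0.25, adjusted p = 4.24e-04, 2 of 3 probe sets with this sign) and THEMIS2 (-1.40, 0.63 and 0.07, adjusted p = 5.74e-04) had theirs in PC-3, and SCNN1G (0.33, -0.02 and -2.36, adjusted p = 5.09e-04) in MKN74. As a list, interferon-stimulated genes differed by a median of -1.11 between PC-3 and MKN74 and -0.91 between HBC4 and MKN74 (camera adjusted p = 7.02e-46 and 4.14e-30), calls lost with an estimated correlation (adjusted p = 0.286 and 0.426). The interaction count fell whichever line was left out: it was 19 without MKN74, 67 without PC-3 and 115 without HBC4. Without 1 array it lay between 78 (reagent alone in MKN74) and 190 ((uuaggg)4 in HBC4). Such fits also hold fewer arrays, and how much of each fall is due to that was not tested. Within lines, 6 of 100 splits of the arrays gave as many genes, the real one included. Of the 6, 3 exchanged only the classes of whole lines, which turns the shared response into an interaction.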

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

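The splits and the tests of shared probe sets and of probe set choice were planned before their results were seen; the tests of RNA quality, of the starting level and of line identity were chosen after. The response to G4 oligonucleotides differed between cell lines for 248 genes by the interaction test, and the 8 genes with the smallest adjusted p were IFI27 (4.94e-05), HOTTIP (4.24e-04), ZBP1 (4.24e-04), IFI6 (5.09e-04), CARD16 (5.09e-04), SCNN1G (5.09e-04), THEMIS2 (5.74e-04) and RTP4 (5.74e-04). Over 100 splits of the arrays within lines, 6 gave 248 genes or more, the real one included, with a highest other of 1203, so chance is not excluded for the count over all of them. Of these, 3 exchanged the classes of a whole line, which turns the shared response into a difference between lines, and 2 were other splits, with at most 272 genes. Set apart after this was seen, these 3 leave 97 splits, of which 3 gave 248 genes or more, so the result over all 100 rests on how such exchanges are counted.

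For the shared response, the model with line and class called 824 genes, and the highest of the other 99 splits called 2. Thus 1 of 100 splits, the real one, reached the real count, which makes chance unlikely without excluding it. In the other splits the real class difference enters the residual spread, which can lower their counts. The comparisons of 2 treatments allow only 4 exchanges within lines, too few for a share under 0.05. The real counts were 48 for (uuaggg)4 and 115 for AS1411, each reached by 1 of 4 exchanges, against a highest other of 0. (uuaccc)4 against the reagent and (uuaggg)4 against AS1411 gave 0 in all 4.

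The fall of interferon-stimulated genes with both G4 oligonucleotides was weighed against 2 technical explanations. Hybridisation shared between related genes is argued against: the 38 members whose probe set carries no mark for shared sequence had a median of -1.96, with quartiles of -2.32 and -1.24, and the 22 marked ones -1.38. RNA quality as the actin 5' to 3' control probe sets read it is argued against as the whole cause: with it as a covariate the list mean still differed by -1.74 (95% interval -2.26 to -1.23), against -1.77 without it. The actin difference (G4 minus control) was -0.06 in PC-3, 0.29 in HBC4 and -0.11 in MKN74, and with GAPDH as the covariate the list mean differed by -1.69; a loss of quality that neither control shows stays open. No untransfected cells were analysed here, so whether the transfected controls had raised these genes, or G4 oligonucleotides lowered them below the resting level, was not tested.

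The smaller fall of interferon-stimulated genes in MKN74 (weakest of the 3 lines for 47 of 60 genes) was weighed next. The choice of probe sets by their spread between lines is argued against, since with averaged probe sets the fall in MKN74 was still smaller by a median of 0.83. A lower starting level was looked for: in the control arrays MKN74 lay at a median of -0.60 relative to the other lines, and in the G4 arrays at 0.01. The fall is the difference of these 2 levels, so a smaller fall shows in them by construction, and the values cannot decide the cause. The fall itself was smaller by a median of 0.97. In the control arrays 37 genes lay below the other lines and 23 above (quartiles -2.21 and 0.45), and the hypothesis was found and tested on the same arrays.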

How the results depend on the processing

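The filter on the spread between line means, the variance prior without trend and the probe set with the largest spread of line means were chosen after the centring was seen; the other alternatives were planned. Results of named genes past the threshold (115) were rerun in 13 of the 29 settings, not without single arrays and not with all probe sets tested, and gave 1064 alternatives: 814 kept direction and side of the threshold, 250 kept the direction only, and 0 reversed. The opposite signs on other probe sets of a named gene, given with the results, are therefore not among these reversals. The median of the interferon-stimulated genes was negative throughout, from -2.30 without MKN74 to -1.44 without PC-3. Quantile normalization of the centred values gave 314 genes for G4 oligonucleotides against controls, 12 for (uuaggg)4, 61 for AS1411, and 229, 1675 and 225 within PC-3, HBC4 and MKN74. With all 41091 probe sets tested the first 3 counts were 879, 89 and 191 probe sets, and PC-3 had 634. A gene can enter these counts more than once. Array weights gave 74 genes for (uuaggg)4. Without the cell line as a block the counts were 1, 0 and 0. Fits on the 6 arrays of 2 treatments gave 10 genes for (uuaggg)4 and 23 for AS1411. With 2 classes in the model G4 oligonucleotides against controls had 824. The filter on spread took the correlation across genes to 0.72. The cause of these changes was not tested, except that the block removes the difference between lines and the 6-array fits hold fewer samples. Leaving out a line or an array gave 48 to 420 genes for G4 oligonucleotides against controls, 2 to 53 for (uuaggg)4, 8 to 102 for AS1411, 153 to 354 in PC-3, 193 to 581 in HBC4, 123 to 328 in MKN74, 19 to 190 for the interaction, and a correlation of 0.52 to 0.63. A lone array left in a line and class was assumed to vary like the others. The counts of 0 for (uuaccc)4 against the reagent and (uuaggg)4 against AS1411 were 0 in each alternative run. The filters at an intensity percentile were not run, since centred values carry no signal level over background.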

Other observations

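The tests in this part were chosen after the values were seen, apart from the markers of 7 cell types. Of 17 type I and III interferon genes 2 fell with G4 oligonucleotides, IFNL1 (log2 fold change -0.72, adjusted p = 0.0197) and IFNL2 (-1.42, adjusted p = 0.0326), and IFNB1 had -0.70 (adjusted p = 0.0637). As a family they had a median of -0.01, 7 were positive, and camera with an estimated correlation gave p = 0.362. Of 56 cytosolic ribosomal protein genes 6 rose and 49 were positive, with a median of 0.11 (0.09 after quantile normalization; camera p = 0.0167 with an estimated correlation). Of 502 zinc finger genes 23 fell and 0 rose, with a median of -0.07 (-0.07 after quantile normalization; camera p = 3.90e-04 with an estimated correlation). These camera p are unadjusted. The chemokine gene CCL5 fell by 2.08 on the log2 scale (adjusted p = 1.84e-04). Markers of other cell types had no member past the threshold: the median log2 fold change with G4 oligonucleotides was -0.00 for fibroblasts, -0.04 for leukocytes, -0.07 for endothelial cells, 0.09 for prostate, 0.02 for breast, 0.14 for gastric and intestinal epithelium and 0.15 for neural cells.

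Between lines, leukocyte markers had a median of 2.53 in HBC4 relative to the mean of the other lines, with 4 of 8 over 2 higher: HLA-DRA (5.70), CD74 (5.48), LYZ (3.24) and CD14 (3.21). The pan-leukocyte marker PTPRC had -0.16 and the T cell markers CD3D and CD3E -0.10 and 0.11.

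The arrays labelled MKN74 also carry a pattern to follow up. Relative to the mean of the other lines, 26 keratinocyte genes had a median of 4.18, among them SPRR1B (9.86), SPRR3 (8.25), ZNF750 (7.19), KRT5 (4.87) and LORICRIN (4.47). Of the 26, 15 were over 2 higher, and DSC3 (-4.94), SERPINB3 (-3.32), KRT14 (-1.62) and KRT10 (-1.12) were lower. The 9 gastric and intestinal markers had a median of -0.01, with CDX2 at 1.56. The medians are consistent with a culture of another identity than its gastric label, but PC-3 itself carries 3 of those 9 markers at a high level, and the values are relative to 2 lines only. The keratinocyte mean differed by 0.23 over the 4 arrays, so keratinocyte-like cells mixed evenly into a gastric culture cannot be told apart from it. The keratinocyte list was written from these arrays, and the identity remains a hypothesis about the label.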
